A study of Homo sapiens with 18 samples.

How the data were processed

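Normal human epidermal keratinocytes, a primary cell type, received DMSO or 0.5 uM PP-2, and total RNA was isolated and labelled with biotin by the Affymetrix 3' protocol, per the labels' protocols. The deposited values are linear intensity values per probe set, summarised with GCRMA per the submitters' processing notes. The GCRMA version, and any scaling after it, are not given in the sources used here. The deposited intensity values run from 8.9 to 689946.7, and most probe sets lie near a floor, so changes from or to that floor depend on its height. The labels give the time and treatment of each array, with the first group's time written with the letter O and read as 0 h. The 18 arrays form 9 groups of 2, described as duplicate treatments. No donor, culture or batch is named, so p-values measure only the spread between these arrays, which may be technical. Between 11 and 98 of 22283 probe sets agreed exactly within a group, and between 3 and 2474 over all 153 pairs of arrays. Of the 2474, 2 lay above log2 8, where that pair, from different groups, differed with an SD of 1.10 log2.

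Values were turned to log2 with no pseudocount. Of 22283 probe sets, 19071 had 1 gene symbol in the platform annotation, 1043 had several and 2169 had none. Symbols of 19059 probe sets were matched through Entrez identifiers to a RefSeq gene table of GRCh38.p14, used only for names. Probe sets with several or no symbols were left out, as were XIST, TSIX and Y-linked genes. Each gene was represented by the probe set with the highest mean log2 value, out of several for 4310 genes. Of the other probe sets with a mean above log2 8 of genes called, 92.8% to 95.3% changed in the same direction. A filter of log2 5 on at least 2 arrays removed 5 of 11939 genes and left 11934.

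A mean per group was fitted over all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend), with 9 residual and 3.399 prior degrees of freedom. Contrasts were PP-2 against DMSO at each of 4 times, their average, the effect at 48 h minus that at 12 h, and DMSO at 48 h against 0 h. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 31 lists within a comparison, and again with a correlation estimated per list and with fry, which tests whether a list's genes move one way on balance. Lists needed at least 5 measured genes. They cover spinous layer differentiation, differentiation transcription factors, cornified envelope, barrier lipid metabolism, kallikreins and protease inhibitors, basal layer, hyperproliferation, S phase, G2 and M phase, p53 targets, EGF receptor and MAP kinase, TGF-beta and matrix, NRF2, unfolded protein and amino acid response, heat shock, Notch, interferon, cytokines, sterol, fatty acid, glycolysis and hypoxia, aryl hydrocarbon receptor, retinoid and vitamin D, tubulin, ribosomal proteins, nucleolus, oxidative phosphorylation, and markers of melanocytes, fibroblasts, leukocytes, and endothelium, sweat gland or simple epithelium. Some genes stand on more than 1 list.

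The groups, contrasts, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule names, per PP-2 comparison, the 10 largest rises and the 10 largest falls past the threshold with both PP-2 arrays (for the average, the group means at all 4 times) on the same side of the DMSO arrays, 5 each way for the difference between times and for DMSO, up to 4 members of each list with the largest change among those past the threshold, and 2 where none passed. Overlaps of calls were tested with Fisher's exact test (one-sided). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

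The model was tested on simulated data for 11934 genes with 50 changed genes of each size. For PP-2 against DMSO at 48 h it recovered 9 of 50 at a log2 change of 0.5, 38 at 1, 50 at 2 and 50 at 4, with 7 unchanged genes called (4.55% of calls). For the average over 4 times it recovered 38, 49, 50 and 50, with 12 unchanged genes called (6.03%).

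Alternatives were all probe sets or their mean per gene, no filter or one at log2 6, a pseudocount of 16, quantile normalization, median centring, eBayes without trend or robust, array weights, only the arrays of the groups compared, each array left out in turn, the replicate number as a block, stricter thresholds, and, chosen after the data were seen, a filter at log2 8, DMSO at 0 h as the control, the DMSO change to 36 h in an overlap, and leaving out arrays with an 18S rRNA signal. Leaving out arrays was run for gene counts and named genes, not for list tests.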

Results

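Primary human epidermal keratinocytes were treated with the vehicle DMSO or with 0.5 uM of PP-2, a small molecule that the labels name only by this code and as compound 9. Expression was measured on 18 single-channel Affymetrix arrays in 9 groups of 2. The groups were DMSO at 0, 12, 24, 36 and 48 h and PP-2 at 12, 24, 36 and 48 h. The series concerns small molecules that induce differentiation of these cells, and the main comparisons ask which genes differed between PP-2 and DMSO cultures of the same age. The median intensity of an array lay between 93.6 and 108.5. Between 54.8% and 58.7% of the probe sets of an array lay below a log2 intensity of 7, near the floor of the values. The arrays of a group correlated at 0.995 to 0.998 across probe sets. The SD of the difference between them was 0.210 to 0.392 log2 over genes with a mean above log2 8, highest for PP-2 at 24 h. Changes are differences of group means in log2 intensity with the SE of the limma model (n = 2 arrays per group), and the number of arrays limits their precision.

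Against DMSO of the same time, 780 of 11934 genes passed an adjusted p of 0.05 at 12 h, 1350 at 24 h, 2040 at 36 h and 2815 at 48 h. At 12 h 382 genes rose and 398 fell, and at 24 h 489 rose and 861 fell. At 36 h 829 rose and 1211 fell, and at 48 h 1316 rose and 1499 fell. Changes of at least 10-fold were found for 9 genes up and 8 down at 12 h, and for 93 up and 73 down at 48 h. The 12 h count moved with single arrays: without replicate 1 of DMSO at 12 h, 510 genes passed, with 209 up and 301 down. Without replicate 2 of DMSO at 12 h, 284 rose and 283 fell, without replicate 1 of PP-2 at 12 h, 303 rose and 459 fell, and without replicate 2 of PP-2 at 12 h, 478 rose and 241 fell. The excess of falls shrank after quantile normalization, with 738 up and 793 down at 24 h and 1050 up and 1141 down at 36 h, and turned at 48 h, with 1465 up and 1438 down. It also turned without replicate 1 of PP-2 at 24 h, with 567 up and 558 down. With array weights 590 genes passed at 24 h, and after median centring 513 passed at 12 h. With the mean of all probe sets of a gene in place of the highest, 146 of 810 named changes past the threshold moved by over 1.5 times. TMT1A then rose by 2.08 and MAF by 1.09 at 12 h, and NRG1 lay at -0.89 for the average over 4 times.

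**Figure D1:**
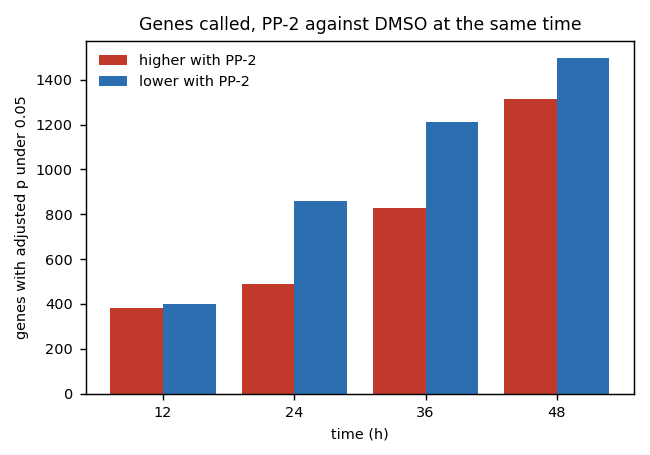
Number of genes with an adjusted p under 0.05 (vertical axis) that were higher (red bars) or lower (blue bars) in PP-2 than in DMSO at 12, 24, 36 and 48 h (horizontal axis). The counts go from 382 higher and 398 lower at 12 h to 1316 higher and 1499 lower at 48 h.

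At 12 h, TMT1A, a methyltransferase, rose by 6.07 ± 0.19 with PP-2. The carbonic anhydrase CA2 rose by 4.73 ± 0.31, the glucocorticoid-induced TSC22D3 by 4.64 ± 0.20 and the stress-induced NUPR1 by 4.43 ± 0.23. The cytochrome P450 CYP1B1 rose by 4.41 ± 0.21 and the selenium carrier SELENOP by 4.24 ± 0.20. The interferon-induced antiviral genes MX1 (-4.75 ± 0.28), IFIT1 (-4.30 ± 0.34) and IFI44 (-4.15 ± 0.17) fell. So did DUSP5 (-3.67 ± 0.38), a phosphatase of ERK, the growth factor VEGFC (-3.64 ± 0.33) and the plasminogen activator PLAT (-3.56 ± 0.16). The adjusted p of the 20 genes with the largest changes by the rule for named genes lay between 4.12e-09 for TMT1A and 0.000917 for MAFF.

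Of the 31 gene lists, 10 were higher and 7 lower at 12 h in limma's camera test, and 9 of these calls hold with an estimated correlation. In the interferon response 16 of 39 members fell and none rose (19 down adjusted over the list alone), with a list p of 1.05e-15. Of the nucleolus and ribosome biogenesis genes 15 of 30 fell (18 down and 1 up adjusted over the list alone), among them NOP16 (-1.65 ± 0.19) and NIP7 (-1.59 ± 0.19). Of the EGF receptor ligands and MAP kinase response genes 11 of 34 fell and 3 rose (14 and 3 adjusted over the list alone). The ligand TGFA (-2.37 ± 0.17) and the urokinase gene PLAU (-2.37 ± 0.15) were among those that fell. G2 and M phase genes rose in 18 of 52 cases (24 up and 1 down adjusted over the list alone). The kinetochore genes NDC80 and CENPF rose by 2.08 ± 0.23 and 2.05 ± 0.33, and the topoisomerase TOP2A by 1.81 ± 0.23. Of the S phase genes 8 of 42 fell and 3 rose (10 and 3 adjusted over the list alone), and the replication factor CDC6 fell (-1.86 ± 0.27). The S phase list had an adjusted p of 0.0862 with an estimated correlation.

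Differentiation transcription factors rose in 5 of 16 cases at 12 h (6 adjusted over the list alone), MAF by 3.19 ± 0.25 and CEBPD by 1.23 ± 0.13. In the list of the spinous layer, which lies above the basal cells, 4 of 14 rose (4 adjusted over the list alone), LY6D by 2.08 ± 0.15. That list had an adjusted p of 0.0619 with an estimated correlation. For the cornified envelope, the protein shell of the outermost cells, 3 of 20 rose (4 adjusted over the list alone), the envelope precursor PPL by 2.24 ± 0.15. The adjusted p was 0.141 with an estimated correlation, and the call ended after quantile normalization and after median centring. The cornified list median was slightly below 0 while its mean and test were above. In the basal layer list 3 of 18 rose (4 up and 1 down adjusted over the list alone), the basal keratin KRT15 by 2.94 ± 0.21, with an adjusted p of 0.18 with an estimated correlation.

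NRF2 oxidative stress genes rose in 6 of 24 cases at 12 h and fell in 1 (6 and 1 adjusted over the list alone). The glutathione synthesis enzyme GCLC rose by 2.04 ± 0.14 and the reductase AKR1C1 by 1.75 ± 0.17. Of the p53 targets and cell cycle inhibitors 7 of 29 rose and 2 fell (9 and 3 adjusted over the list alone), DDB2, a DNA damage sensor, by 1.33 ± 0.23. Cytosolic ribosomal protein genes rose in 10 of 42 cases (22 adjusted over the list alone) with a list median of 0.20. Tubulin genes fell in 6 of 14 cases (6 adjusted over the list alone). The aryl hydrocarbon receptor targets (4 of 12 up, 1 down) and the heat shock response (7 of 16 down, 1 up) had an adjusted p of 0.0788 and 0.0619 with an estimated correlation. Oxidative phosphorylation (4 of 33 up, 1 down) and sterol biosynthesis (3 of 18 down) had an adjusted p of 0.345 and 0.258 with an estimated correlation. With only the arrays of 12 h in the fit, 209 genes passed.

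At 24 h, the inositol phosphatase IMPA2 rose by 6.88 ± 0.39, TMT1A by 6.38 ± 0.19 and the IGF-binding protein IGFBP3 by 6.11 ± 0.19. The glycoprotein GPNMB rose by 5.78 ± 0.15 and the arginine synthesis enzyme ASS1 by 5.54 ± 0.17. PLAT (-6.06 ± 0.16), MX1 (-5.12 ± 0.28), the matricellular protein CCN2 (-4.85 ± 0.56) and the matrix protease ADAMTS1 (-4.75 ± 0.23) fell, as did the inducible cyclooxygenase PTGS2 (-3.79 ± 0.32). All of these 10 genes had an adjusted p of 7.22e-05 or less.

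Spinous layer genes rose in 9 of 14 cases at 24 h (10 adjusted over the list alone), with a list p of 7.14e-13. LY6D rose by 5.21 ± 0.15 and the desmosomal cadherins DSC1 and DSC2 by 3.74 ± 0.50 and 3.02 ± 0.20. Of the differentiation transcription factors 7 of 16 rose (8 adjusted over the list alone), MAF by 5.05 ± 0.25 and ZNF750, a regulator of late epidermal differentiation, by 4.05 ± 0.19. Cornified envelope genes rose in 4 of 20 cases (5 adjusted over the list alone), PPL by 3.04 ± 0.15 and SPRR1B by 1.33 ± 0.07. Kallikreins and epidermal protease inhibitors rose in 5 of 20 cases and fell in 1 (6 and 1 adjusted over the list alone), SERPINB13 by 2.35 ± 0.24. Of the aryl hydrocarbon receptor targets 4 of 12 rose and 1 fell (5 and 1 adjusted over the list alone), CYP1B1 by 5.15 ± 0.21 and ALDH3A1 by 3.58 ± 0.12. Camera did not call these targets later, with 3 up and 3 down at 36 h and 3 up and 6 down at 48 h. Fry called them higher at both later times, although the median at 48 h was -0.23. Ribosomal protein genes rose in 15 of 42 cases (22 adjusted over the list alone). Of the p53 targets 7 of 29 rose and 2 fell (7 and 5 adjusted over the list alone). Hyperproliferation and alarm keratin genes rose in 4 of 11 cases and fell in 1 (4 and 1 adjusted over the list alone), KRT16 by 2.14 ± 0.17, with an adjusted p of 0.115 with an estimated correlation.

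Interferon response genes fell in 18 of 39 cases at 24 h (20 adjusted over the list alone). Of the TGF-beta response, matrix and mesenchymal genes 8 of 31 fell and 1 rose (10 and 1 adjusted over the list alone), with the thrombospondins THBS2 (-3.01 ± 0.33) and THBS1 (-2.63 ± 0.17) lower. In the EGF receptor and MAP kinase list 13 of 34 fell and 2 rose (15 and 2 adjusted over the list alone), including SPRY2 (-2.96 ± 0.41), a feedback inhibitor of that pathway. S phase genes fell in 16 of 42 cases (21 adjusted over the list alone), CDC6 (-2.88 ± 0.27) and the ribonucleotide reductase subunit RRM2 (-1.90 ± 0.14) among them. Nucleolus genes fell in 15 of 30 cases (19 down and 1 up adjusted over the list alone) and tubulin genes in 9 of 14 (10 adjusted over the list alone). The 13 lists named so far for 24 h, hyperproliferation aside, hold with an estimated correlation.

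In the unfolded protein and amino acid response 14 of 33 fell and 5 rose at 24 h (14 and 5 adjusted over the list alone). The endoplasmic reticulum chaperone HSPA5 (-3.07 ± 0.08) and HERPUD1 (-2.84 ± 0.10) fell, while NUPR1 rose by 4.61 ± 0.23. Of all 33, 15 were lower and 7 higher than DMSO at 0 h. That list had an adjusted p of 0.108 with an estimated correlation, and the NRF2 list (5 of 24 up, 2 down) one of 0.0772. The heat shock (6 of 16 down, 3 up) and sterol (5 of 18 down) lists had an adjusted p of 0.188 with an estimated correlation, and both calls ended after quantile normalization. The G2 and M phase list, with 5 of 52 up and 6 down, did not pass.

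Some arrays carried a ribosomal RNA signal. The control probe set for 18S rRNA lay between log2 11.48 and 15.15 on 7 arrays, 3 of DMSO and 4 of PP-2, and at 7.04 or below on the others. The 7 were every array of 12 h, 1 DMSO and 1 PP-2 array of 24 h and 1 PP-2 array of 36 h. Without these arrays, an alternative chosen after the data were seen, 443 genes rose and 462 fell at 24 h, and 1807 passed at 36 h. This leaves 1 array against 1 at 24 h and 1 PP-2 array at 36 h, so the spread comes from the other groups, and at 12 h no array is left. The 3' minus 5' difference of the actin control probe sets, a sign of RNA quality, moved with the treatment: at each of the 4 times both PP-2 arrays lay above both DMSO arrays. It was 1.46 and 1.13 log2 against 1.05 and 1.01 at 12 h, 1.36 and 1.24 against 0.96 and 0.99 at 24 h, 0.97 and 0.94 against 0.75 and 0.77 at 36 h, and 1.12 and 1.15 against 0.90 and 0.91 at 48 h. That of the GAPDH control was higher on both PP-2 arrays at 12 and 36 h and lower on both at 24 and 48 h.

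At 36 h, GPNMB rose by 8.85 ± 0.15, IGFBP3 by 8.60 ± 0.19, LY6D by 8.04 ± 0.15 and the epidermal chemokine CXCL14 by 7.94 ± 0.33. The desmosomal cadherins DSC1 and DSG1 rose by 7.04 ± 0.50 and 6.85 ± 0.40, and KRT1, the keratin of suprabasal cells, by 6.85 ± 0.22. KRT1 lay at 5.53 in DMSO and 12.37 in PP-2, so its change depends on where the floor of the values lies. PLAT (-7.27 ± 0.16), G0S2 (-6.39 ± 0.38), an inhibitor of fat breakdown, CCN2 (-5.59 ± 0.56), VEGFC (-5.56 ± 0.33) and the EGF receptor ligand EREG (-5.33 ± 0.42) fell. The adjusted p of these 12 genes was at most 1.09e-05.

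Spinous layer genes rose in 10 of 14 cases at 36 h (10 adjusted over the list alone) with a median of 2.79. Of the cornified envelope genes 10 of 20 rose (10 up and 1 down adjusted over the list alone), the small proline-rich SPRR1A by 2.40 ± 0.11 and the cross-linking enzyme TGM1 by 1.87 ± 0.05. Kallikreins and epidermal protease inhibitors, which act in shedding of the outer layer, rose in 10 of 20 cases and fell in 2 (11 and 2 adjusted over the list alone). KLK5 rose by 3.49 ± 0.07 and KLK7 by 3.25 ± 0.35. Differentiation transcription factors rose in 8 of 16 cases and fell in 1 (9 and 1 adjusted over the list alone), ZNF750 by 6.49 ± 0.19 and HOPX by 3.42 ± 0.51. Of the barrier lipid genes 6 of 17 rose and 1 fell (7 and 1 adjusted over the list alone), the cholesterol sulfotransferase SULT2B1 by 3.36 ± 0.10, with an adjusted p of 0.103 with an estimated correlation. The hyperproliferation list (5 of 11 up, 1 down) had an adjusted p of 0.0632 with an estimated correlation.

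In the unfolded protein and amino acid response 25 of 33 fell and 3 rose at 36 h (25 and 3 adjusted over the list alone), with a median of -1.81. TRIB3 (-4.06 ± 0.27), a pseudokinase induced by ATF4, and the chaperone DNAJB9 (-4.04 ± 0.32) fell. Of all 33, 16 were lower and 5 higher than DMSO at 0 h, against which the list median was -0.39 at 36 h, with an adjusted p of 0.131 with an estimated correlation. Interferon genes fell in 19 of 39 cases and rose in 1 (19 and 1 adjusted over the list alone). The EGF receptor and MAP kinase list had 19 of 34 down and 1 up (20 and 2 adjusted over the list alone). In the TGF-beta, matrix and mesenchymal list 11 of 31 fell and 2 rose (13 and 2 adjusted over the list alone), among them the intermediate filament VIM (-3.84 ± 0.27). S phase genes fell in 17 of 42 cases (21 adjusted over the list alone) and nucleolus genes in 17 of 30 (19 adjusted over the list alone). Of the lists so far for 36 h, 10 hold with an estimated correlation. G2 and M phase genes fell in 24 of 52 cases (29 adjusted over the list alone), NDC80 (-1.43 ± 0.23) among them, with an adjusted p of 0.103 with an estimated correlation. The tubulin (8 of 14 down, 1 up) and ribosomal protein (6 of 42 up) lists had an adjusted p of 0.128 and 0.261 with an estimated correlation.

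At 48 h, IGFBP3 rose by 10.20 ± 0.19, GPNMB by 9.99 ± 0.15, LY6D by 8.94 ± 0.15 and CXCL14 by 8.91 ± 0.33. DSC1 rose by 8.74 ± 0.50, KRT1 by 8.46 ± 0.22 and DSG1 by 8.14 ± 0.40. The uridine phosphorylase UPP1 (-8.93 ± 0.18), G0S2 (-8.35 ± 0.38), VIM (-7.78 ± 0.27), the TGF-beta pseudoreceptor BAMBI (-7.52 ± 0.08), TRIB3 (-7.42 ± 0.27) and the collagenase MMP1 (-7.28 ± 0.17) fell. All 13 had an adjusted p of 2.64e-08 or less. BAMBI lay at 6.07 in PP-2 at 48 h, 13.59 in DMSO at 48 h and 6.16 in DMSO at 0 h, and MMP1 at 6.67, 13.94 and 7.03. VIM lay at 7.08 in PP-2 at 48 h, 14.86 in DMSO at 48 h and 14.73 in DMSO at 0 h.

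**Figure D2:**
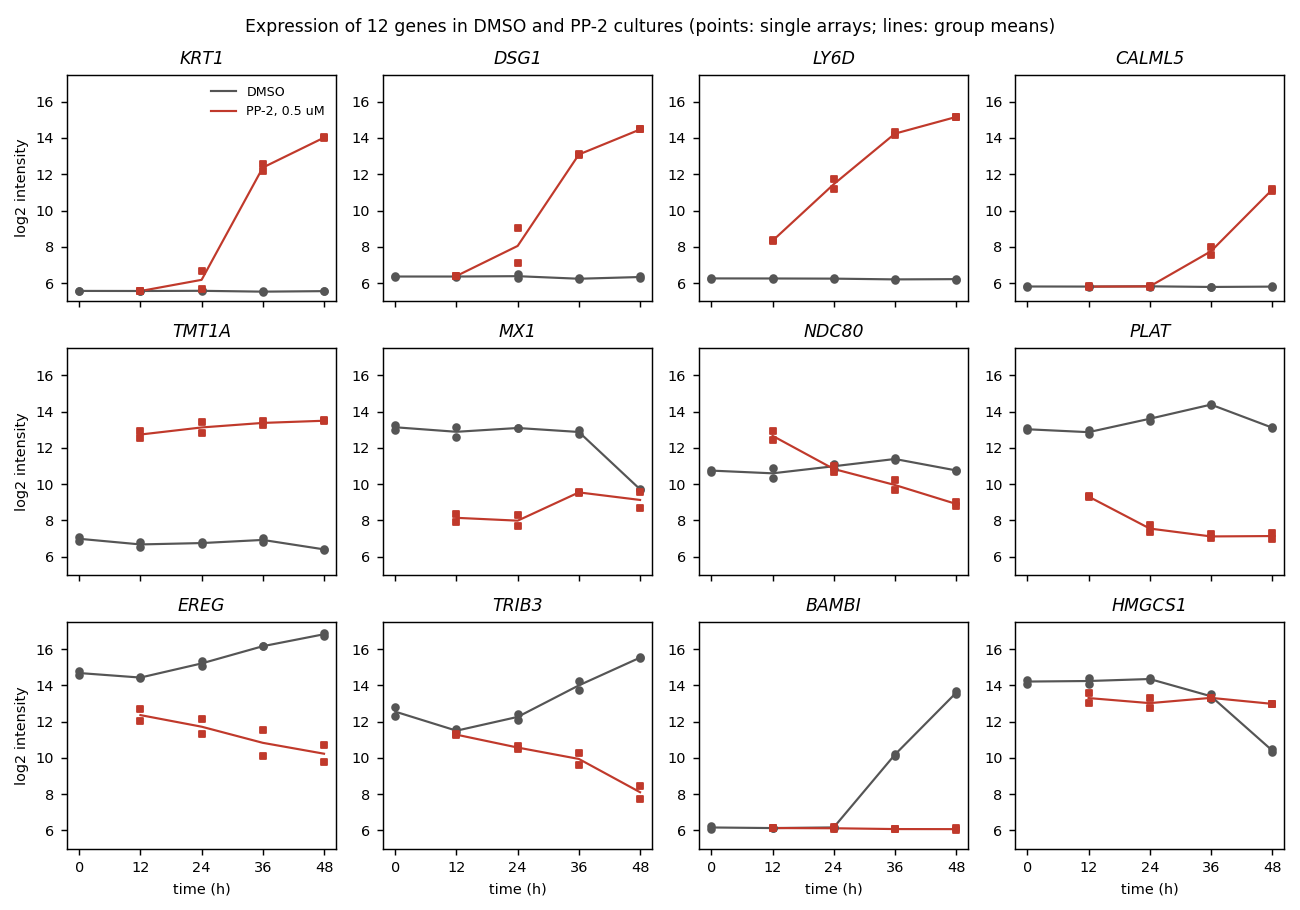
Log2 intensity (vertical axis) against time in h (horizontal axis) of 12 genes, a selection made after their values were seen, in DMSO and PP-2 cultures, with a point per array and lines through the group means. KRT1 stays between 5.53 and 5.57 in DMSO and reaches 14.02 in PP-2 at 48 h, while BAMBI reaches 13.59 in DMSO and lies at 6.07 in PP-2 at 48 h.

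Spinous layer genes rose in 11 of 14 cases at 48 h (11 adjusted over the list alone) with a median of 3.94. Cornified envelope genes rose in 13 of 20 cases and fell in 1 (13 and 1 adjusted over the list alone). The calmodulin-like CALML5 rose by 5.35 ± 0.10, SCEL by 4.26 ± 0.25 and SPRR3 by 3.23 ± 0.20. Chosen after their values were seen, the envelope genes FLG, LORICRIN and IVL rose by 2.38 ± 0.11, 1.63 ± 0.19 and 0.79 ± 0.11. Of the kallikreins and epidermal protease inhibitors 10 of 20 rose and 2 fell (10 and 2 adjusted over the list alone), KLK7 by 6.16 ± 0.35 and SERPINB3 by 5.59 ± 0.27. Of the differentiation transcription factors 7 of 16 rose and 2 fell (7 and 2 adjusted over the list alone), MAF by 6.62 ± 0.25. SULT2B1 rose by 4.74 ± 0.10 and KRT16 by 3.86 ± 0.17. Their lists, barrier lipid (8 of 17 up, 1 down) and hyperproliferation (5 of 11 up, 2 down), had an adjusted p of 0.0628 and 0.0964 with an estimated correlation. The hyperproliferation median was slightly below 0 while its mean and test were above.

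Sterol biosynthesis genes rose in 16 of 18 cases at 48 h (16 adjusted over the list alone) with a median of 1.67. HMGCS1, which makes HMG-CoA, rose by 2.56 ± 0.21 and the sterol-responsive INSIG1 by 2.50 ± 0.22. HMGCS1 lay at 12.98 in PP-2 at 48 h, 10.41 in DMSO at 48 h and 14.21 in DMSO at 0 h. In the unfolded protein and amino acid response 27 of 33 fell and 1 rose (28 and 1 adjusted over the list alone), with ATF3 (-6.33 ± 0.06) and the asparagine synthetase ASNS (-5.38 ± 0.19) lower. In the EGF receptor and MAP kinase list 20 of 34 fell (22 down and 1 up adjusted over the list alone), DUSP5 (-6.86 ± 0.38) and EREG (-6.60 ± 0.42) among them. The median of that list was -1.21, and -0.28 against DMSO at 0 h, with 14 down and 2 up. In the TGF-beta, matrix and mesenchymal list 18 of 31 fell and 2 rose (18 and 3 adjusted over the list alone), and THBS2 fell (-5.74 ± 0.33). With the spinous, cornified, kallikrein and transcription factor lists, 8 lists hold with an estimated correlation. The interferon list (8 of 39 down, 5 up, the same adjusted over the list alone) was not called by camera, with a list p of 0.51, while fry, which compares no other genes, called it lower with an adjusted p of 0.000257. MX1 lay at 9.13 in PP-2 at 48 h, 9.72 in DMSO at 48 h and 13.14 in DMSO at 0 h.

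G2 and M phase genes fell in 26 of 52 cases at 48 h and rose in 4 (27 and 4 adjusted over the list alone), with CDC20 (-3.93 ± 0.25), an activator of mitotic exit, lower, and an adjusted p of 0.206 with an estimated correlation. The mitotic kinase AURKA fell (-2.54 ± 0.27) on the probe set used and was 1.00 higher, past the threshold, on another. S phase genes rose in 13 of 42 cases and fell in 5 (14 and 6 adjusted over the list alone), the thymidylate synthase TYMS by 2.71 ± 0.19, with an adjusted p of 0.0964 with an estimated correlation. Heat shock genes rose in 8 of 16 cases and fell in 1 (8 and 1 adjusted over the list alone), the small heat shock proteins CRYAB and HSPB1 by 6.42 ± 0.40 and 3.67 ± 0.14, with an adjusted p of 0.0628 with an estimated correlation. The adjusted p with an estimated correlation was 0.0694 for NRF2 genes (10 of 24 up, 3 down), 0.185 for oxidative phosphorylation (17 of 33 up, 1 down) and 0.171 for fatty acid synthesis (6 of 12 up, 1 down). It was 0.206 for glycolysis and hypoxia (11 of 31 up, 8 down) and 0.0781 for p53 targets (12 of 29 up, 5 down), whose median was slightly below 0 and mean and test above. It was 0.105 for nucleolus (14 of 30 down), 0.211 for tubulin (5 of 14 up, 2 down) and 0.335 for ribosomal protein genes (8 of 42 up, 1 down), the last call also ending after quantile normalization.

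**Figure D3:**
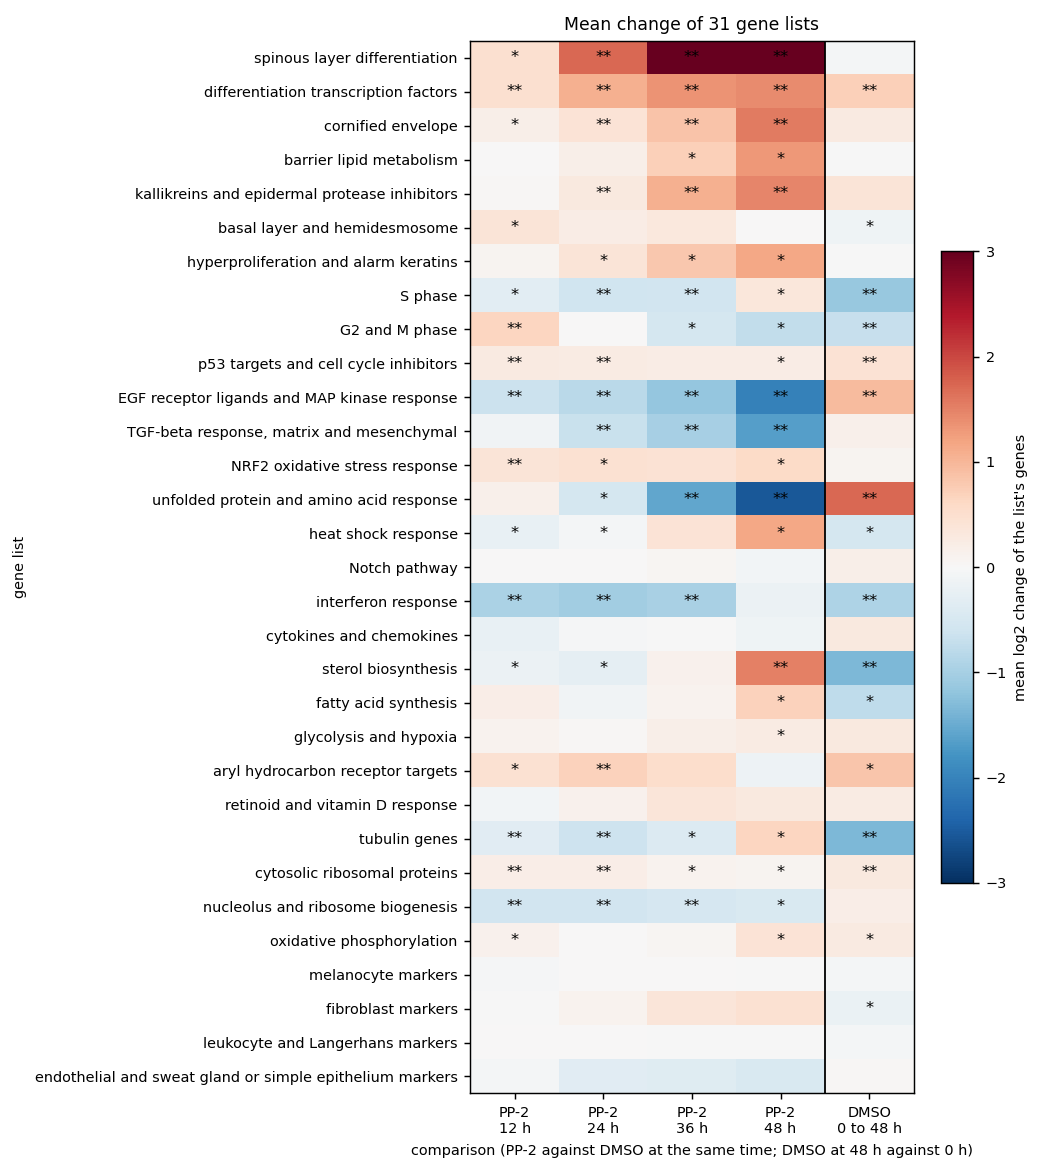
Mean log2 change (colour, limited at 3 in either direction) of 31 gene lists (vertical axis) in PP-2 against DMSO at 12, 24, 36 and 48 h and in DMSO at 48 h against 0 h (horizontal axis), with * for an adjusted p under 0.05 in the camera test and ** where it holds with an estimated correlation. The mean of the spinous layer list goes from 0.49 at 12 h to 4.48 at 48 h, and that of the unfolded protein and amino acid list is -2.55 at 48 h and 1.73 in DMSO.

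No melanocyte marker of 12 and no leukocyte or Langerhans marker of 17 passed limma's test at 12, 24, 36 or 48 h, and 0 had an unadjusted p under 0.05. Most lay near the floor, with OCA2, MITF, EDNRB, CD1C and HLA-DPB1 above log2 7 in some group. The largest changes at 48 h were 0.11 ± 0.16 for OCA2 and 0.10 ± 0.26 for CD1C. The fibroblast list did not pass camera or fry against DMSO of the same time, but its member DCN, a matrix proteoglycan, rose by 3.71 ± 0.37 at 36 h and 4.48 ± 0.37 at 48 h. Of the markers of endothelium, sweat gland and simple epithelium 3 of 15 fell and 1 rose at 48 h. Camera did not call that list (adjusted p 0.164 at 48 h), while fry called it lower at 24, 36 and 48 h (adjusted p 0.00335, 0.00362 and 0.000256), with a median slightly above 0 at 36 h. The simple epithelial keratins KRT7 (-3.32 ± 0.20), KRT18 (-2.58 ± 0.14) and KRT19 (-1.29 ± 0.10) fell at 48 h. The Notch, cytokine and retinoid lists passed at none of the 4 times in camera, while fry called the cytokine list lower at 48 h (adjusted p 0.000989) and the retinoid list higher at 36 h (0.0165). In all fry called 1 list at 12 h, 3 at 24 h, 8 at 36 h and 4 at 48 h that camera did not. At 48 h 3 of 15, 6 of 32 and 4 of 24 of their members rose and 2, 8 and 3 fell, with IL1B (-4.75 ± 0.14) and CXCL2 (-5.30 ± 0.14) lower and the retinoic acid carrier CRABP2 higher by 5.67 ± 0.27.

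The comparison of DMSO at 48 h with DMSO at 0 h asks how the vehicle cultures changed with time. BAMBI rose by 7.43 ± 0.08, PTX3 by 6.93 ± 0.16, MMP1 by 6.91 ± 0.17, STC2 by 6.87 ± 0.12 and the stress-induced transcription factor ATF3 by 6.31 ± 0.06. IFIT1 (-5.99 ± 0.34), TUBA1A (-5.54 ± 0.18), TMEM97 (-5.11 ± 0.35), the transferrin receptor TFRC (-4.39 ± 0.21) and IFI44 (-4.30 ± 0.17) fell. In all 1559 genes rose and 613 fell, and after quantile normalization 1091 rose and 1122 fell. The median change of genes above log2 8 was 0.13.

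Of the unfolded protein and amino acid response genes 22 of 33 rose with time in DMSO (22 adjusted over the list alone). Of the EGF receptor and MAP kinase genes 15 rose and 1 fell of 34 (18 and 1 adjusted over the list alone), the ligand HBEGF by 2.68 ± 0.18. S phase genes fell in 29 of 42 cases (29 adjusted over the list alone), TYMS (-3.42 ± 0.19) among them. G2 and M phase genes fell in 25 of 52 cases and rose in 2 (28 and 2 adjusted over the list alone), with the mitotic kinase CDK1 (-3.20 ± 0.18) lower. Sterol biosynthesis genes fell in 13 of 18 cases (14 adjusted over the list alone), INSIG1 (-4.15 ± 0.22) among them. Interferon genes fell in 14 of 39 cases and rose in 1 (17 and 2 adjusted over the list alone), and tubulin genes fell in 10 of 14 (10 adjusted over the list alone). Ribosomal protein genes rose in 25 of 42 cases (34 adjusted over the list alone) and differentiation transcription factors in 6 of 16 (6 adjusted over the list alone), CEBPD by 2.76 ± 0.13. The p53 list (10 of 29 up, 1 down) passed but not after quantile normalization. These 10 lists hold with an estimated correlation.

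In DMSO the adjusted p was 0.0824 with an estimated correlation for the heat shock (6 of 16 down) and fatty acid (7 of 12 down) lists. It was 0.192 for aryl hydrocarbon receptor targets (5 of 12 up) and 0.411 for the basal layer (3 of 18 up, 7 down). It was 0.485 for oxidative phosphorylation (10 of 33 up, 2 down) and fibroblast markers (2 of 15 down), a pair of calls also lost after quantile normalization. The spinous layer list had 2 of 14 up and 2 down and a list p of 0.7.

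Set against DMSO at 0 h, a control added after the data were seen, 776 genes passed in PP-2 at 12 h, 1346 at 24 h, 1935 at 36 h (1243 up, 692 down) and 2459 at 48 h (1583 up, 876 down). Of the 1499 genes lower than DMSO at 48 h, 572 (38.2%) were also lower than DMSO at 0 h and 80 were higher. Of the 1316 higher genes 974 (74.0%) were also higher than DMSO at 0 h and 44 were lower. Part of these overlaps may come from the PP-2 arrays at 48 h, which both comparisons share. Of the lower genes 894 had risen in DMSO to 48 h and of the higher genes 322 had fallen, but these counts share the DMSO arrays at 48 h with opposite sign. With the DMSO change to 36 h, which shares no arrays and was added after the data were seen, the counts were 418 against 127.2 expected for independent calls, and 43 against 19.3. Only 294 of 2815 calls at 48 h had a mean below log2 7, so counts expected over all 11934 genes are likely too low. Spinous layer genes were higher in 11 of 14 cases and cornified envelope genes in 14 of 20. S phase genes were lower in 25 of 42 cases and G2 and M phase genes in 37 of 52, with list p values of 0.00676 and 0.0123 with an estimated correlation. The EGF receptor and MAP kinase list had a median of -0.16 at 36 h, with an adjusted p of 0.211 with an estimated correlation, and of -0.28 at 48 h, with one of 0.0447. The nucleolus list had one of 0.215 at 36 h, with a median of -0.19. For ribosomal proteins the adjusted p with an estimated correlation was 0.0803 at 12 h and 0.104 at 24 h, but 0.0138 at 36 h and 0.0159 at 48 h. For aryl hydrocarbon receptor targets it was 0.104 at 24 h. At 48 h the median of the TGF-beta, matrix and mesenchymal list was -0.36, and those of the tubulin and fatty acid lists lay below 0, at -0.72 and -0.10, while they lay above 0 against DMSO at 48 h.

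The test of the difference between the PP-2 effects at 48 h and 12 h asks which responses changed over time. IGFBP3 (9.39 ± 0.27), GPNMB (9.15 ± 0.21), CXCL14 (8.89 ± 0.47) and KRT1 (8.46 ± 0.30) had a higher effect at 48 h. VIM (-7.84 ± 0.39), the cystine transporter SLC7A11 (-7.57 ± 0.29) and BAMBI (-7.52 ± 0.12) had a lower one. SLC7A11 rose by 1.92 ± 0.20 at 12 h and fell (-5.64 ± 0.20) at 48 h. In all 872 genes had a higher and 970 a lower effect at 48 h, and after quantile normalization 1007 and 972. The excess of lower effects also turned without replicate 1 of PP-2 at 12 h (884 and 824) or at 48 h (846 and 836). Of the G2 and M phase genes 33 of 52 had a lower effect (38 adjusted over the list alone), NDC80 (-3.93 ± 0.32) among them. Unfolded protein and amino acid genes had a lower effect in 29 of 33 cases (29 adjusted over the list alone). Camera called 12 lists higher and 4 lower, of which 12 hold with an estimated correlation. The others were interferon (13 of 39 up, 3 down), fatty acid (5 of 12 up, 1 down), tubulin (6 of 14 up) and oxidative phosphorylation (8 of 33 up), with an adjusted p of 0.0588, 0.344, 0.0617 and 0.368 with an estimated correlation.

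The average asks for the mean effect over the 4 times, which also takes in genes that changed at only some of them. TMT1A rose by 6.50 ± 0.10, IGFBP3 by 6.43 ± 0.10, GPNMB by 6.37 ± 0.07, CA2 by 6.22 ± 0.16 and LY6D by 6.07 ± 0.08. PLAT (-5.72 ± 0.08), G0S2 (-5.41 ± 0.19), VEGFC (-4.90 ± 0.17), DUSP5 (-4.72 ± 0.19) and NRG1 (-4.44 ± 0.09), a ligand of ERBB receptors, fell. In all 1392 genes were higher and 1835 lower (1700 and 1788 after quantile normalization), of which 639 changed at least 2-fold and 1475 by less than 0.5 log2. Spinous layer genes rose in 11 of 14 cases (11 adjusted over the list alone), and EGF receptor and MAP kinase genes fell in 23 of 34 and rose in 3 (23 and 3 adjusted over the list alone). Camera called 11 lists higher and 6 lower, of which 11 hold with an estimated correlation. The adjusted p with an estimated correlation was 0.1 for the barrier lipid and NRF2 lists, 0.103 for hyperproliferation, 0.193 for S phase, 0.0619 for sterol biosynthesis and 0.279 for oxidative phosphorylation.

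The overlap of calls asks whether early and late responses involve the same genes. Of the 382 genes up at 12 h, 236 (61.8%) were also up at 24 h, against 15.7 expected for independent lists (one-sided Fisher's exact p = 1.61e-249). Of the 398 down at 12 h, 306 (76.9%) were also down at 24 h, against 28.7 expected (one-sided Fisher's exact p = 3.53e-285). From 12 h to 48 h, 58.1% of rises and 59.3% of falls were shared, and 52 genes up and 40 down at 12 h were called in the opposite direction at 48 h. The comparisons at different times share no arrays, but they share an estimate of spread per gene. Few genes near the floor were called: 16 of 780 calls at 12 h and 30 of 1350 at 24 h had a mean below log2 7. Expected counts over all 11934 genes are therefore too low. Genes that move together are also not independent, so the Fisher's exact p-values overstate the evidence for the overlap. At all 4 times 166 genes were up, among them TMT1A, CA2 and LY6D, and 187 were down, among them PLAT. Across 4850 genes with a mean above log2 8, which are not independent replicates, the changes correlated at 0.753 between 12 h and 24 h, 0.826 between 36 h and 48 h and 0.437 between 12 h and 48 h. Across 11934 genes, the PP-2 effects at 12, 24 and 36 h correlated with the DMSO change to 48 h at 0.123, 0.0506 and -0.141 (Spearman's rho 0.16, 0.00707 and -0.145). The effect at 48 h correlated with the DMSO change to 36 h at -0.226 (rho -0.0254), and these 4 pairs share no arrays.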

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

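The tests of the unfolded protein, sterol and interferon patterns, and those of time course progress and 18S rRNA signal for the PP-2 pair at 24 h, were chosen only after the results were seen.

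The PP-2 effect differed between 48 h and 12 h in 1842 genes by the test of the difference itself. It was higher at 48 h for IGFBP3 (9.39), GPNMB (9.15), CXCL14 (8.89), KRT1 (8.46) and DSC1 (8.23), and lower for VIM (-7.84), SLC7A11 (-7.57), BAMBI (-7.52), UPP1 (-7.30) and TRIB3 (-7.21). The lists that differed with an estimated correlation were higher at 48 h by a median of 3.56 for the spinous layer, 1.16 for the cornified envelope, 0.28 for barrier lipid metabolism and 0.33 for kallikreins and protease inhibitors. The medians were 0.45 for hyperproliferation, 0.47 for S phase, 1.13 for the heat shock response and 1.67 for sterol biosynthesis. They were -1.32 for G2 and M phase, -0.90 for the EGF receptor and MAP kinase list, -0.64 for the TGF-beta, matrix and mesenchymal list and -2.43 for the unfolded protein and amino acid response. These effects are set against DMSO cultures that changed with time. Against DMSO at 0 h, the S phase median was -0.05 in PP-2 at 12 h, -0.70 in PP-2 at 48 h and -0.89 in DMSO at 48 h. The S phase list thus did not rise in PP-2. The heat shock median was -0.40 in PP-2 at 12 h, 0.06 in PP-2 at 48 h (3 up, 3 down) and -0.29 in DMSO at 48 h. Outside the measurement of genes, the 18S rRNA control probe set reached log2 15.15 and lay over 1 log2 above the DMSO arrays at 0 h on 7 arrays.

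The unfolded protein and amino acid list was lower and the sterol list higher with PP-2 at 48 h, while in DMSO from 0 h to 48 h their medians were 1.09 and -1.34. The PP-2 and DMSO cultures compared had the same age, so a change with time common to both would give no difference. DMSO at 0 h as the control asks instead which arm moved from the starting level. For the unfolded protein list, a difference made only by the rise in DMSO is argued against at 48 h. There PP-2 was also lower than DMSO at 0 h, with a median of -0.65 against -2.26 for DMSO at 48 h. The camera adjusted p against DMSO at 0 h was 0.0309 with an estimated correlation. The mean change of the list was -2.55 against DMSO at 48 h, and in DMSO from 0 h to 48 h it was 1.73. The larger part of the difference at 48 h thus lay in the rise in DMSO. At 24 and 36 h the list was not called against DMSO at 0 h with an estimated correlation (adjusted p 0.104 and 0.131). Of members that fell on 1 PP-2 array at 24 h, 12 of 14 and 11 of 12 lay below DMSO at 0 h on the other. At 36 h these were 14 of 23 and 15 of 25. For those members a difference made only by the change in DMSO is argued against, and for the others it stays open. These shares are not shown to be particular to the list. Of all genes called at 24 and 36 h, 84.67% and 61.32% also passed against DMSO at 0 h, in either direction and with the same PP-2 arrays. The arrays were near equal in scale, with median intensities at 48 h of 102.1 and 98.7 in DMSO and 101.1 and 96.6 in PP-2. The list median was -2.30 after quantile normalization, which changed the counts of other genes, and -2.24 after median centring. Remaining differences in scale between arrays are argued against as the whole cause. With arrays so alike these settings could change the list little, and they do not test scaling done before deposit. For sterol biosynthesis the median against DMSO at 0 h was 0.31, with an adjusted p of 0.321 with an estimated correlation. Of members that rose on 1 PP-2 array, 4 of 16 and 2 of 15 were higher than DMSO at 0 h on the other, and 3 and 2 were lower. The difference at 48 h thus lay mostly in a fall in DMSO. In PP-2 at 48 h the list as a whole had not fallen, with 5 members higher and 3 lower than DMSO at 0 h. Why the list fell in DMSO and not with PP-2 was not tested.

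The interferon list was lower with PP-2 at 12, 24 and 36 h and was not called by camera at 48 h (p 0.51), while fry called it lower there (adjusted p 0.000257). A return of the PP-2 cultures to the starting level is argued against, since at 48 h the list was below DMSO at 0 h with a median of -0.60 and an adjusted p of 0.00528 with an estimated correlation. A later fall in the DMSO cultures may account for the smaller difference, whose test against 12 h gave an adjusted p of 0.0588 with an estimated correlation: DMSO at 48 h was below DMSO at 0 h with a median of -0.11, a mean of -0.92, 14 members down and 1 up, and an adjusted p of 0.00895 with an estimated correlation. Why interferon genes fell in DMSO was not tested.

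The PP-2 arrays at 24 h differed more than other pairs, with an SD of the difference of 0.392. The shape of the value distribution is argued against, since quantile normalization changed the excess over the other pairs by -12.04 percent in the direction of removal, from 0.130 to 0.146. Different progress along the PP-2 time course may play a part but cannot be told apart from its absence, as the correlation with the change from 12 h to 36 h was 0.183, between the bounds set for either outcome. The same holds for the 18S rRNA signal on array 1, with a correlation of 0.181 with the DMSO pair that shares it. Over 36 pairs of groups such correlations ranged from -0.436 to 0.294, and 10 lay over 0.1, so 0.181 does not stand out. No biological explanation was tested.

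Other splits of the PP-2 and DMSO arrays within time were drawn for the average over 4 times. Of 100 splits out of 648, 3 gave as many genes, the real one included, with 3227 genes for the real split and 4447 for the highest other. Both other splits of the 3, with 4447 and 3395 genes, exceeded the real one. A draw of 100 also leaves the share over all 648 uncertain. Of the other splits drawn, 0 kept the arrays of every group together. Each thus put PP-2 and DMSO arrays of some time into the same group. That adds the treatment difference to the spread, and the median count of these splits was 0 genes. If the duplicates are technical, such splits do not stand for regrouped treatments, so chance is not excluded. In the highest other split 89.4% of the genes had a mean below log2 7 and the median change was 0.0477 in size. In a count chosen after the splits were seen, 639 genes changed at least 2-fold in the real split, 1 in the split with 4447 genes, 24 in that with 3395, and at most 496 in any other split drawn.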

How the results depend on the processing

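The filter at log2 8, DMSO at 0 h as the control, the DMSO change to 36 h and leaving out arrays with an 18S rRNA signal were chosen only after the data were seen. Of 810 named changes past the threshold, picked as large changes in the same data, none reversed under the 11 settings run on them. Most settings could not reverse any. The filters, the eBayes variants, array weights, only the arrays compared and the replicate block leave the log2 changes as they are. Past the threshold 744 stayed with only the arrays compared, 776 with median centring and 791 with array weights. With the mean of probe sets 796 stayed, and at least 801 under the others. By over 1.5 times 146 of them moved with the mean of probe sets and 12 with quantile normalization. Under the other 9 settings 0 did, but most of those leave the log2 changes fixed. Gene counts stayed within 1.5 times except as follows, and the cause was not tested unless given.

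At 12 h 513 genes passed after median centring, and 209 with only the arrays compared. With only the arrays compared, 967 passed at 24 h, 2053 at 36 h and 3131 at 48 h. Fewer arrays thus did not lower the count at every time, and the cause at 12 h was not tested. The SD of the difference between the PP-2 arrays was 0.331 at 12 h and 0.392 at 24 h, against 0.298 at 36 h and 0.267 at 48 h. At 24 h array weights gave 590. An adjusted p under 0.01 gave 442 at 12 h and 890 at 24 h, as a stricter threshold must give fewer. At least 2-fold changes numbered 337, 593, 911 and 1385 at 12, 24, 36 and 48 h, 639 for the average, 1202 for the difference between times and 946 in DMSO, again by construction. All probe sets, which are more tests, gave 3213 at 36 h, 4410 at 48 h, 5137 for the average, 2854 for the difference and 3434 in DMSO. Leaving out an array, with the lone array assumed to vary like the other groups, gave 510 to 762 genes at 12 h, and ended the call of 27 of 106 named genes at 12 h and 4 of 120 at 48 h with no change of sign.

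With an estimated correlation, 9 lists passed at 12 h, 8 at 48 h, 11 for the average and 10 in DMSO, and with fry, which compares no genes outside the list, 23 at 36 h and 26 for the average. Over called genes alone the correlations of the PP-2 effect with the DMSO change were 0.206 at 12 h, 0.124 at 24 h and -0.336 at 48 h. With the replicate block 754, 1319, 1998 and 2802 genes passed at 12, 24, 36 and 48 h, though replicate numbers did not pair the arrays: the PP-2 and DMSO deviations correlated at -0.179, 0.181, -0.0128 and 0.0199 at 12, 24, 36 and 48 h, and 36 pairs of groups ranged from -0.436 to 0.294. Signal over background limits the folds of genes at the floor, and 294 of 2815 calls at 48 h had a mean below log2 7.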

Other observations

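No test in this part was chosen after the result it measures was seen, but the hypothesis came from genes already seen to rise at 12 h.

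TSC22D3, RGS2, SELENOP, BNIP3L and BTG1, which FOXO transcription factors are known to induce, rose at 12 h by 4.64 ± 0.20, 3.36 ± 0.28, 4.24 ± 0.20, 2.30 ± 0.23 and 1.64 ± 0.15. The call of BTG1 ended with only the arrays of 12 h in the fit, and with the mean of its probe sets TSC22D3 rose by 2.43. The hypothesis that they may be part of a common FOXO target response was tested on a list of 27 other targets, of which 22 were measured. The list median at 12 h was 0.13, at percentile 99.89 of 10000 random lists matched on mean expression. The random lists do not allow for targets that move together, so the percentile overstates the evidence. The test also used the same arrays that gave the hypothesis. Of its members 3 rose and 1 fell: TXNIP (2.10 ± 0.13), KLF9 (1.14 ± 0.29) and RBL2 (0.91 ± 0.14) were higher and KLF6 (-1.14 ± 0.17) was lower. IGFBP1, PCK1 and PDK4 lay at -0.01 ± 0.10, -0.08 ± 0.12 and -0.01 ± 0.05. The list median was 0.06 at 24 h, with 5 up and 1 down, 0.14 at 36 h, with 6 up and 2 down, and -0.02 at 48 h, with 5 up and 4 down. The median shift is small and most members did not pass, and no measure of FOXO itself was tested.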
